A study of Aspergillus nidulans with 12 samples.

How the data were processed

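The 12 arrays fall in 6 groups, 3 strains at 10 and 30 min of calcium. Per the labels, mycelium of Aspergillus nidulans from a 16 h preculture was moved to 25 mL of fresh YAG medium with 200 mM CaCl2 at 30 °C, and treated RNA (Cy5) was hybridised against untreated preculture RNA of the same strain (Cy3) on a 2-colour array. All labels give 1 dye orientation. Part of the protocol text in the labels mentions a different treatment, and the groups here follow the sample titles and treatment fields. The labels do not say which gene the scrA- allele lies in, or whether untreated cultures were shared between arrays. By their barcodes the arrays lie on 3 slides, 1 per strain.

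The deposited scanner files, made by the authors with Agilent Feature Extraction 9.5.3.1, hold spot and local background signals as intensity in scanner units. Per the file headers, processed signals in the same files are an intensity after spatial detrending and dye normalization. Per the file headers, the log ratio column is log10 of processed red over processed green. The other deposited columns used are flags of 0 or 1 per spot for signal well above background, saturation and outliers. The deposited value table of the series is on a log2 scale, settled from its values: against log2 of red over green from the scanner files its correlation was 0.996 to 0.998 and its slope 1.00 to 1.01. How the authors centred that table is not given in the sources used here. The genome build behind the probes is not given in the sources used here either, so no coordinates are reported.

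Scanner signals were read and analysed with limma 3.58.1 in R 4.3.3, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Mean signals were background-corrected with normexp (offset 50) and normalised by loess within each array, with control spots at weight 0 and no scaling between arrays. An array held 45220 spots, 43803 of them not controls. Spots marked as non-uniform or population outliers were left out, which removed 2.83 to 5.82% of spots per array. The array has 1 probe per gene for 11143 genes, and spots of a gene were averaged, usually 4 or 3. A gene was tested when at least 0.5 of its spots were marked well above background in at least 1 channel on at least 2 arrays. This left 8636 genes, 16 of which lacked a value on at least 1 array. The offset pulls the ratios of dim genes towards 0. A fold is printed as a lower bound when the dimmer channel was not well above background on any array of the group.

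Signal was compared with local background on each array. The median Cy3 signal per array was 75.5 to 119 and the median Cy5 signal 95.3 to 226, over median backgrounds of 35 to 37 and 36 to 37.5. Saturated Cy5 spots numbered 5 to 98 per array, and no Cy3 spot was saturated. The spread of log2 ratios on an array had an SD of 0.46 to 0.66, and the spike-in controls had a slope of 0.87 to 0.92 against their known log ratios. The number of arrays limits the precision: each group has 1 to 3.

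Gene identifiers on the array were matched to a RefSeq table of assembly ASM1142v1, used for symbols only; 10443 matched and 700 did not. A symbol was found for 774 genes, 738 of them tested. The description column of the array files reads Unknown for its genes, so lists defined by words in a description had no members.

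A mean per group was fitted to the 12 arrays, with 6 residual degrees of freedom, a prior of 2.55 degrees of freedom from empirical Bayes, and 2-sided moderated tests. Adjusted p is by Benjamini and Hochberg within each of 12 contrasts, and a gene is called below 0.05. The contrasts were the response of each of the 6 groups, the change from 10 to 30 min in wild type and in the double mutant, the differences of ΔcrzA and of the double mutant from wild type at 10 min, the difference between the mutants at 10 min, and that of the double mutant from wild type at 30 min. All groups were given the same spread per gene, so for ΔcrzA at 30 min the single array was assumed to vary like the other groups. No contrast compares 3 or more arrays with 3 or more, so regrouping of samples was not tested. The adjusted p values measure the spread between these arrays.

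Gene lists were tested with camera (preset correlation 0.01), and again with the correlation estimated from the data, with adjustment over the 19 lists of a contrast. No list call in any contrast held with the estimated correlation, except that with each member taken by ID (11 lists) the calcium list was lower in both mutants than in wild type at 10 min. Lists needed at least 5 tested members. The first 10 were fixed by gene ID before the data were examined: calcium signalling and transport, cell wall, osmotic stress and glycerol, conidiation (chosen to stand in for another cell type, though mostly regulators were bright enough to test), the sterigmatocystin cluster, the penicillin, terrequinone and orsellinic acid clusters, nitrogen assimilation, glycolysis and fermentation, gluconeogenesis with acetate and ethanol use, and iron uptake. A member whose ID carries another symbol in the table was moved to the symbol's own ID or dropped, so midA is AN4897, and AN8842, cbpA, ace1, pmr1 and cch1 are reported outside the calcium list. The cell wall list as fixed gave AN7032 for chsA and AN4566 for chsC. The table names AN4566 chsA and AN7032 chsB, and the table's names are used here. The other 9 lists were added afterwards and chosen by symbol alone, without their values: ribosome biogenesis, cytosolic ribosomal proteins, proteasome, ergosterol synthesis, cell wall, chaperones, plant polysaccharide hydrolases, siderophores and iron, and septins, polarity and cytoskeleton.

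Genes were named by a rule fixed with the lists. It takes crzA, the tested calcium genes for responses, the 4 largest rises and 4 largest falls among called genes with the same sign on each array (for differences, no overlap between the groups' arrays), the 8 largest each way among those with a symbol, and up to 4 members of a list with the largest absolute change. A gene named in 1 contrast may be given in the others.

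The overlap of both mutants' differences from wild type was compared with independent lists and with 50 simulated data sets that share the wild-type arrays' error and hold no true difference. The pipeline was tested on simulated data with 200 changed genes per comparison. At log2 1 it called 96% of changed genes for wild type at 10 min, 72% for ΔcrzA at 30 min and 70% for each mutant's difference from wild type at 10 min; false calls were 2.08 to 7.33% of calls, with no wrong sign. A simulated list shift of 0.5 was recovered, and 0 of 20 unshifted lists were called. Simulated errors were independent between arrays and between genes, with the same spread in all groups. These results hold under those assumptions and do not show that the real arrays meet them.

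Alternatives tried were no background correction, Agilent's processed signals, median centring in place of loess, scaling between arrays, the authors' log2 table, no filter and a stricter filter on dim genes, only the arrays of a contrast, array weights, slide as a random block, the replicate number as a block, an absolute log2 ratio of at least 1, and each array left out in turn. Aquantile scaling between arrays, which leaves the log ratios unchanged, was tried too. Blocks for a shared control culture, and lists with each member taken by ID, were added after seeing the data.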

Results

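The series measured gene expression in Aspergillus nidulans after a calcium pulse in wild type, in a strain lacking crzA (ΔcrzA), and in a strain combining the crzA deletion with a scrA- allele (ΔcrzA scrA-, called the double mutant here). On each of 12 arrays, RNA from calcium-treated mycelium was labelled with Cy5 and RNA from the untreated 16 h preculture of the same strain with Cy3. The pulse was 200 mM CaCl2 for 10 or 30 min at 30 °C. There were 2 arrays for wild type at 10 min, 2 for wild type at 30 min, 3 for ΔcrzA at 10 min, 1 for ΔcrzA at 30 min, 2 for the double mutant at 10 min and 2 for the double mutant at 30 min. The labels call the arrays of a group biological replicates. A response is given as log2(Cy5/Cy3), so positive values mean more RNA after calcium than in the preculture. A gene was called when its limma adjusted p was below 0.05.

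Signal covered most of the genome on every array. Of 11143 genes on the array, 8636 gave signal well above local background and were tested. Between 66.3 and 72.9% of genes were well above background in Cy3, and between 67.2 and 74.1% in Cy5. Replicate arrays correlated across genes at r = 0.94 for wild type at 10 min, 0.74 for wild type at 30 min, 0.82 to 0.91 for ΔcrzA at 10 min, 0.67 for the double mutant at 10 min and 0.74 at 30 min; genes are not independent replicates. Every array carried calcium in Cy5, so a gene's dye bias is part of each response and drops out only where strains or times are compared. The mycelium was also moved to fresh medium with the calcium, and no array measured the move alone. Each strain sat on a slide of its own, so strain and slide could not be told apart, while both times of a strain shared a slide.

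The crzA probe (AN5726) separated wild type from both mutants. In wild type it was well above background in both channels on 4 of 4 arrays, with mean Cy3 signals of 63.6 to 89.3 and Cy5 signals of 122 to 196 over a local background of 33.9 to 36.1. In the mutants it was well above background on 0 of 8 arrays, with Cy3 signals of 40.7 to 44.8 and Cy5 signals of 42.7 to 49.4 over a background of 35.4 to 38.2. In wild type crzA itself was higher at 10 min of the pulse than in the preculture (log2 0.53, SE 0.09, adjusted p = 0.0030), and at 30 min its value was 0.20 (SE 0.09, adjusted p = 0.15). Nothing on the arrays checked the scrA- allele, because the labels do not say which gene it lies in.

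**Figure D1:**
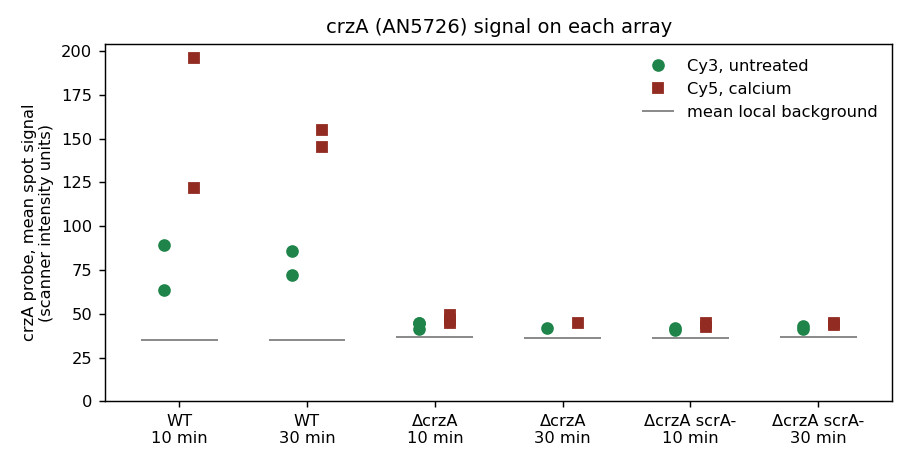
Mean spot signal of the crzA probe in scanner intensity units on each array, by strain and time, with Cy3 (untreated) as circles, Cy5 (calcium) as squares and the mean local background as a line. All 4 wild-type arrays lie at 63.6 or above in both channels, and all 8 mutant arrays lie at 49.4 or below.

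In wild type, the calcium genes pmcB, vcxA and cbpA rose by 10 min of the pulse, while the calcium pump gene pmr1 fell. The calcium-transporting ATPase gene pmcB (AN4920) rose 20.4-fold, the calcium/proton exchanger gene vcxA (AN0471) 4.45-fold, and the calcipressin gene cbpA (AN6249) 7.37-fold. The chitin synthase gene chsA (AN4566) rose 9.27-fold, and most tested genes for making ribosomes fell. In all, 2286 of 8636 genes were called (26.5%), 1329 higher and 957 lower. Among them 493 were higher and 203 lower by an absolute log2 ratio of at least 1. The largest rises seen on both arrays were AN2427 (4.83, SE 0.29, adjusted p = 1.4e-05), mfsA (AN9168; 4.71, SE 0.34, adjusted p = 3.2e-05), AN10288 (4.59, SE 0.24, adjusted p = 9.3e-06) and pmcB (4.35, SE 0.42, adjusted p = 1.5e-04). The trehalase gene treA (AN9340) rose by 4.08, and the sterol reductase gene erg4A (AN2684) by 2.51. The largest falls were AN5069 (−2.88, SE 0.27, adjusted p = 1.4e-04), tmpA (AN0055; −2.60, SE 0.49, adjusted p = 0.0050), AN5067 (−2.49) and AN7674 (−2.40).

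Several calcium genes rose in wild type at 10 min, and pmr1 fell. Of 12 tested members of the calcium signalling and transport list, 5 rose, 0 fell and 7 were not called, and 5 rose and 0 fell when adjusted over the list alone. Besides pmcB and vcxA, the rises were the calmodulin-dependent kinase gene cmkA (AN2412; 0.81, SE 0.16, adjusted p = 0.0057), midA (AN4897; 0.57, SE 0.09, adjusted p = 0.0021) and crzA. The list was called higher by camera (median 0.20, adjusted p = 0.043), and was not called with an estimated correlation between genes (adjusted p = 0.48). Outside the list, AN8842 rose (1.09, adjusted p = 0.0034), ace1 (AN2919) rose (0.79, adjusted p = 0.029), and pmr1 (AN7464) fell (−0.96, SE 0.14, adjusted p = 0.0014). AN8842 was the ID first fixed for midA, and which of AN4897 and AN8842 is the gene meant was not settled. The calmodulin gene camA (−0.04), the calcineurin genes cnaA (−0.03) and cnaB (−0.08), and cmkB (−0.07), pacC (0.21) and cch1 (0.12) were not called. The sodium-pump gene enaA (AN6642) was not called at 10 min (0.19, adjusted p = 0.75), and enaB (AN1628) was not well above background in either channel.

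Ribosome biogenesis fell at 10 min in wild type while osmotic-stress genes rose. Of 24 ribosome biogenesis genes, 17 fell and 0 rose (median −1.05, or −1.82 with Agilent processed signals; camera adjusted p = 2.9e-08; with the estimated correlation 0.48). Its largest falls were erb1 (AN1367; −1.98, SE 0.28, adjusted p = 0.0014), nop7 (−1.62), rok1 (−1.57, SE 0.21, adjusted p = 9.5e-04) and rrp3 (−1.47). Of 5 osmotic stress and glycerol genes, 3 rose, including when adjusted over the list alone: the glycerol-3-phosphate dehydrogenase gene gfdB (1.92, adjusted p = 6.1e-05), tpsA (1.45) and gldB (1.16). That list had a median of 1.16 (camera adjusted p = 0.0084; with the estimated correlation 0.48). In ergosterol synthesis, 9 of 19 genes fell and 3 rose (median −0.51, camera adjusted p = 0.013; with the estimated correlation 0.48), but the median was 0.03 with arrays centred on their median. Squalene synthase gene erg9 (AN10396; −1.81, SE 0.31, adjusted p = 0.0034) and erg5 (AN4042; −1.67, SE 0.17, adjusted p = 1.8e-04) fell, against the rise of erg4A. Among siderophore and iron genes, 3 of 14 fell (median −0.27, camera adjusted p = 0.023; with the estimated correlation 0.48), led by mirD (−1.10, adjusted p = 0.0060).

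The remaining lists were not called as lists in wild type at 10 min. In the fixed cell wall list 2 of 6 genes rose, and 2 when adjusted over the list alone, chsA and the chitinase gene chiB (2.40); its camera adjusted p was 0.18. Conidiation genes had 5 of 10 tested members higher, and 5 higher and 1 lower when adjusted over the list alone (median 0.22, camera adjusted p = 0.29). Most tested members are regulators such as flbC, and brlA, wetA, vosA, dewA and rodA were too dim to be tested, so the list says little about conidia. Gluconeogenesis genes had 3 of 8 higher, with the carbon catabolite repressor gene creA at 1.70 (list median 0.91, camera adjusted p = 0.071). Camera adjusted p was 0.25 for glycolysis and fermentation, 0.72 for nitrogen assimilation, 0.097 for the fixed iron list, 0.82 for the sterigmatocystin cluster and 0.97 for the penicillin, terrequinone and orsellinic acid clusters. It was 0.093 for cytosolic ribosomal proteins, 0.090 for the proteasome, 0.72 for the cell wall list built from symbols, 0.61 for chaperones, 0.34 for plant polysaccharide hydrolases and 0.13 for septins, polarity and cytoskeleton. The number called in wild type at 10 min was 1145 without its replicate 1, 697 without its replicate 2 and 3443 when only the arrays of the contrast were fitted.

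After 30 min of calcium in wild type, pmcB and vcxA were still raised and the sodium-pump genes had risen. There pmcB stood 12.6-fold and vcxA 4.95-fold above the preculture, and enaA, not called at 10 min, stood 14.3-fold above it. Ribosome biogenesis genes were back near their preculture level, and some ergosterol genes were lower than in the preculture. In all, 1890 of 8636 genes were called (21.9%), 1256 higher and 634 lower, with 385 higher and 82 lower by an absolute log2 ratio of at least 1. The largest rises seen on both arrays were AN4151 (5.04, SE 0.49, adjusted p = 2.5e-04), AN6535 (4.76, SE 0.24, adjusted p = 1.1e-05), AN8956 (4.49, SE 0.48, adjusted p = 4.0e-04) and AN0903 (4.28, SE 0.14, adjusted p = 3.9e-06). The sodium-pump gene enaA rose by 3.83 (SE 0.36, adjusted p = 2.3e-04), and enaB rose at least 4.26-fold, a bound because its preculture signal was not well above background on either array. The largest falls were AN7142 (−3.24, SE 0.24, adjusted p = 6.8e-05), AN2436 (−2.50), AN3479 (−2.35) and AN11609 (−2.31), and aclA (AN2435), for a subunit of ATP citrate lyase, also fell (−2.22, SE 0.17, adjusted p = 8.1e-05).

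At 30 min in wild type camera called 3 of 19 lists higher and 2 lower, and 0 with the estimated correlation. In the calcium list, 7 of 12 genes rose, 0 fell and 5 were not called, also when adjusted over the list alone (median 0.33, camera adjusted p = 2.0e-04; with the estimated correlation 0.079). They were enaA, pmcB, vcxA, enaB, cmkA (1.23, adjusted p = 9.8e-04), midA (0.34) and pacC (0.32), and outside the list cbpA rose by 1.25 (SE 0.22, adjusted p = 0.0048). Osmotic stress genes had 3 of 5 higher, or 4 when adjusted over the list alone (median 1.39, camera adjusted p = 0.0026; with the estimated correlation 0.43). In ergosterol synthesis 10 of 19 genes fell and 2 rose (median −0.63, camera adjusted p = 1.3e-04; with the estimated correlation 0.23), among them erg5 (−1.77), erg6 (−1.67) and erg13 (−1.56). That median was −0.07 with arrays centred on their median and −0.41 without wild type 30 min replicate 1. In the proteasome list 8 of 15 rose (median 0.25, camera adjusted p = 2.2e-04; with the estimated correlation 0.43), with rpn8 at 0.67. Among septin, polarity and cytoskeleton genes 8 of 20 fell and 2 rose (median −0.19, camera adjusted p = 0.0033; with the estimated correlation 0.52); the septin genes aspC (−1.26), aspD (−1.25) and aspA (−1.22) fell and the fimbrin gene sac6 rose (1.26). Ribosome biogenesis had 0 of 24 genes called (median 0.18, camera adjusted p = 0.50), and conidiation had 1 of 10 higher (median −0.09, camera adjusted p = 0.70). The number called was 1194 without wild type 30 min replicate 1, 855 without replicate 2 and 277 when only the arrays of the contrast were fitted.

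Without crzA, the 10 min pulse still changed many genes. The calcium gene pmcB rose 4.32-fold and vcxA 1.26-fold, cbpA rose less far than in wild type, and cmkA fell. Ribosome biogenesis genes fell and mfsA and treA rose here too. In ΔcrzA, 3719 of 8636 genes were called (43.1%), 1876 higher and 1843 lower, with 421 higher and 276 lower by an absolute log2 ratio of at least 1. This group had 3 arrays and wild type 2, so its larger count does not show a wider response. Called genes with an absolute log2 ratio of at least 1 numbered 697 in ΔcrzA and 696 in wild type. The largest rises were mfsA (4.40, SE 0.27, adjusted p = 1.5e-05), AN6397 (3.70), AN8975 (3.59) and AN9173 (3.48), and the largest falls were AN5069 (−2.27), AN10943 (−2.18), AN7674 (−2.17) and AN4298 (−2.05). In the calcium list 3 of 12 genes rose and 2 fell, also when adjusted over the list alone (median 0.01, camera adjusted p = 0.81). The rises were pmcB (2.11, SE 0.34, adjusted p = 0.0016), midA (0.73, adjusted p = 1.4e-04) and vcxA (0.33, SE 0.12, adjusted p = 0.049), and the falls were cnaB (−0.60, adjusted p = 0.0048) and cmkA (−0.38, SE 0.13, adjusted p = 0.038). Outside the list cbpA rose by 0.83 (SE 0.18, adjusted p = 0.0063), and pmr1 fell (−0.99, adjusted p = 3.2e-04).

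Ribosome biogenesis was the 1 list called in ΔcrzA at 10 min. There 21 of 24 genes fell (median −1.17, or −1.90 with the authors' log2 values; camera adjusted p = 1.4e-07; with the estimated correlation 0.72), led by erb1 (−1.92, SE 0.23, adjusted p = 4.0e-04) and nop7 (−1.90). Osmotic stress genes had 3 of 5 higher (median 0.79, camera adjusted p = 0.11), ergosterol genes 11 of 19 lower and 5 higher (median −0.45, camera adjusted p = 0.15), and conidiation genes 5 of 10 higher and 1 lower (median 0.35, camera adjusted p = 0.20). The conidiation regulator gene flbC rose by 2.36 (SE 0.17, adjusted p = 2.8e-05), and chiB rose by 2.07. The number called was 2395 without ΔcrzA 10 min replicate 2 and 2230 without replicate 3.

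At 30 min, ΔcrzA was measured on 1 array, with no replicate spread of its own. The p values here assume that it varies like the other groups, and they do not show that a value would repeat. On that array the sodium-pump gene enaA stood 19-fold above the preculture (4.25), and enaB was at 1.76. Under the assumption both were called (adjusted p = 0.023), among 210 of 8633 genes (2.43%), 134 higher and 76 lower. Among called genes the largest values besides enaA were AN12177 (3.53), AN6397 (3.33) and AN4870 (3.17), and the lowest were AN7142 (−2.44), AN5467 (−1.84), exgO (AN0779; −1.78) and AN6237 (−1.76). The value of pmcB was 2.05 (adjusted p = 0.089) and that of vcxA was −0.07 (adjusted p = 0.86). The count rests on the spread of other groups: limma called 0 without wild type 10 min replicate 1, 0 without wild type 10 min replicate 2, 85 without ΔcrzA 10 min replicate 2 and 336 without ΔcrzA 10 min replicate 3.

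The list results of ΔcrzA at 30 min come from the same array and the same assumption. The calcium list had a median of 0.11 (2 of 12 genes higher, or 3 when adjusted over the list alone; camera adjusted p = 0.030; with the estimated correlation 0.49). Osmotic stress had a median of 0.53 (1 of 5 higher, or 2 when adjusted over the list alone; camera adjusted p = 0.037; with the estimated correlation 0.68). Chaperones had a median of 1.04 (camera adjusted p = 0.0086; with the estimated correlation 0.49). Ribosome biogenesis (median 0.42, camera adjusted p = 0.021; with the estimated correlation 0.73) and the proteasome (median 0.15, camera adjusted p = 0.019; with the estimated correlation 0.68) were higher by camera with 0 members called. Ergosterol synthesis had 2 of 19 lower (median −0.36, camera adjusted p = 0.013; with the estimated correlation 0.49), and septins, polarity and cytoskeleton had 1 of 20 lower (median −0.06, camera adjusted p = 0.037; with the estimated correlation 0.68), a call that held in 10 of 21 alternatives.

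In the double mutant at 10 min, the response resembled that of ΔcrzA. Again mfsA and treA rose far, ribosome biogenesis fell, and of the calcium transporters vcxA rose while pmcB was not called. In all, 1970 of 8636 genes were called (22.8%), 1101 higher and 869 lower, with 330 higher and 127 lower by an absolute log2 ratio of at least 1. The largest rises were mfsA (3.65, SE 0.34, adjusted p = 2.1e-04), AN9173 (3.64), treA (3.11, SE 0.43, adjusted p = 0.0016) and AN8591 (3.1), and the falls included AN7674 (−1.92), AN11773 (−1.88), AN4864 (−1.83) and tmpA (−1.78). The stress kinase gene sakA (AN1017; 1.78, SE 0.11, adjusted p = 4.8e-05), the transcription factor gene atfB (AN6849; 1.80) and creA (AN6195; 1.81, SE 0.18, adjusted p = 2.9e-04) rose. Among calcium genes 2 of 12 rose and 1 fell, or 3 and 2 when adjusted over the list alone (median 0.04, camera adjusted p = 0.48); vcxA rose (0.52, SE 0.14, adjusted p = 0.031), midA rose (0.62), cnaB fell (−0.49), and pmcB was not called (1.23, SE 0.42, adjusted p = 0.065). Osmotic stress genes had 3 of 5 higher, also when adjusted over the list alone (median 1.13, camera adjusted p = 0.0092; with the estimated correlation 0.62). Ribosome biogenesis had 9 of 24 lower (median −0.83, camera adjusted p = 3.9e-06; with the estimated correlation 0.62), and conidiation had 5 of 10 higher and 1 lower (median 0.35, camera adjusted p = 0.18). The ribosome biogenesis median was −1.30 without double mutant 10 min replicate 1, −0.37 without its replicate 2 and −1.61 with Agilent processed signals. The number called was 534 without replicate 2, and limma called 0 when only the arrays of the contrast were fitted.

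By 30 min in the double mutant, the sodium-pump genes had risen as they had in wild type. The log2 ratio was 3.98 for enaA (SE 0.36, adjusted p = 2.5e-04) and 2.12 for enaB (SE 0.15, adjusted p = 9.6e-05). In all, 2356 of 8636 genes were called (27.3%), 1301 higher and 1055 lower, with 374 higher and 141 lower by an absolute log2 ratio of at least 1. Other large rises were AN8956 (4.18), AN8975 (3.83) and AN4151 (3.18), and the largest falls were AN7142 (−2.50), AN2821 (−2.40), AN8915 (−2.32) and AN3813 (−2.17). Nitrate reductase gene niaD (−1.68, SE 0.40, adjusted p = 0.015) and nitrite reductase gene niiA (−1.59, SE 0.24, adjusted p = 0.0023) fell, in a nitrogen assimilation list with 3 of 17 lower (median −0.30, camera adjusted p = 0.051). The calcium list had 8 of 12 higher and 0 lower, also when adjusted over the list alone (median 0.42, camera adjusted p = 0.0075; with the estimated correlation 0.23), with cmkA at 1.07 (SE 0.16, adjusted p = 0.0020), pmcB at 1.49 (SE 0.42, adjusted p = 0.029) and vcxA at 0.64 (SE 0.14, adjusted p = 0.012). The value of cbpA was 0.36 (adjusted p = 0.26), not called.

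Several other lists were called in the double mutant at 30 min. Osmotic stress genes had 3 of 5 higher (median 1.35, camera adjusted p = 0.032; with the estimated correlation 0.73), and proteasome genes 4 of 15 higher and 1 lower (median 0.17, camera adjusted p = 0.032; with the estimated correlation 0.77). Ergosterol genes had 10 of 19 lower and 1 higher (median −0.63, camera adjusted p = 7.6e-04; with the estimated correlation 0.32), led by erg6 (−1.51). Septin, polarity and cytoskeleton genes had 9 of 20 lower and 2 higher (median −0.22, camera adjusted p = 0.027; with the estimated correlation 0.73), with aspD at −1.23. Conidiation had 2 of 10 higher (median 0.08, camera adjusted p = 0.71). The number called was 1383 without double mutant 30 min replicate 1, 827 without replicate 2 and 556 when only the arrays of the contrast were fitted.

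**Figure D2:**
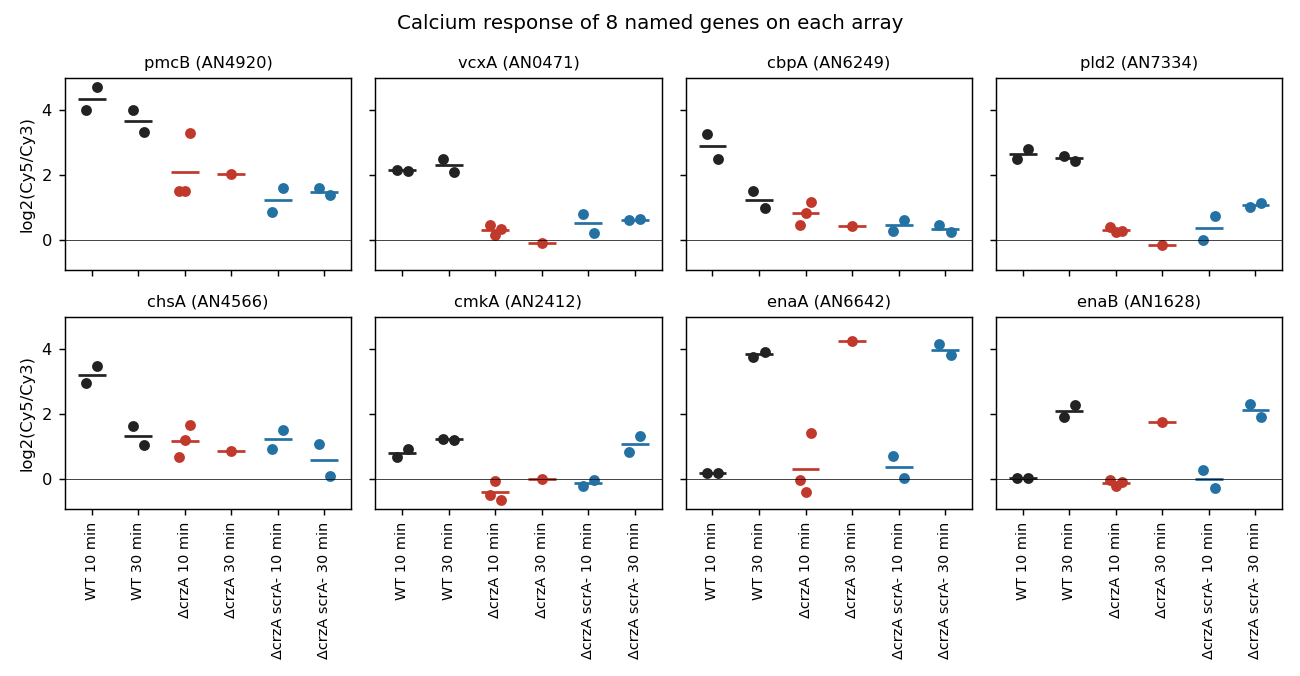
Response as log2(Cy5/Cy3) of 8 genes on each array, by strain and time, with points for arrays and lines for group means. At 10 min the group means of pmcB, vcxA, cbpA and pld2 are lower in both mutants than in wild type (for pmcB the difference was not called), while enaA and enaB reach similar levels at 30 min in every strain.

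The time course in wild type brought the sodium-pump genes up and ribosome biogenesis back. Between 10 and 30 min the increases of enaA (adjusted p = 0.0067) and enaB (adjusted p = 0.0027) were called. Their fitted values are not exact sizes, because at 10 min enaA was not well above background in Cy3 and enaB in neither channel. In the other direction, the early rises of cbpA (−1.63, SE 0.31, adjusted p = 0.019) and chsA (−1.87, SE 0.42, adjusted p = 0.034) receded. In all, 682 of 8636 genes were called (7.90%), 424 higher and 258 lower at 30 min, but fitting only the arrays of this contrast left 1 gene called. The largest increases were AN8956 (4.19, SE 0.68, adjusted p = 0.011), AN7674 (3.31) and AN4298 (2.92), and the largest decreases AN9074 (−2.60), AN10350 (−2.34) and AN8237 (−2.18), leaving out genes with a channel not well above background. AN6404, whose Cy3 signal was not well above background at 30 min, was also called lower. The decrease of creA was −1.73 (adjusted p = 0.0077). In ribosome biogenesis 4 of 24 genes increased (median 1.27, or 0.60 without wild type 30 min replicate 2; camera adjusted p = 7.9e-10; with the estimated correlation 0.65), including rok1 (2.13, SE 0.30, adjusted p = 0.0066) and erb1 (2.01, SE 0.40, adjusted p = 0.023). The calcium list had 2 of 12 higher (median 0.13, camera adjusted p = 0.24), and conidiation 2 of 10 lower (median −0.12, camera adjusted p = 0.24). The count was 210 without wild type 10 min replicate 1, 80 without its replicate 2, 1055 without wild type 30 min replicate 1, 128 without its replicate 2 and 419 without ΔcrzA 10 min replicate 2.

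**Figure D3:**
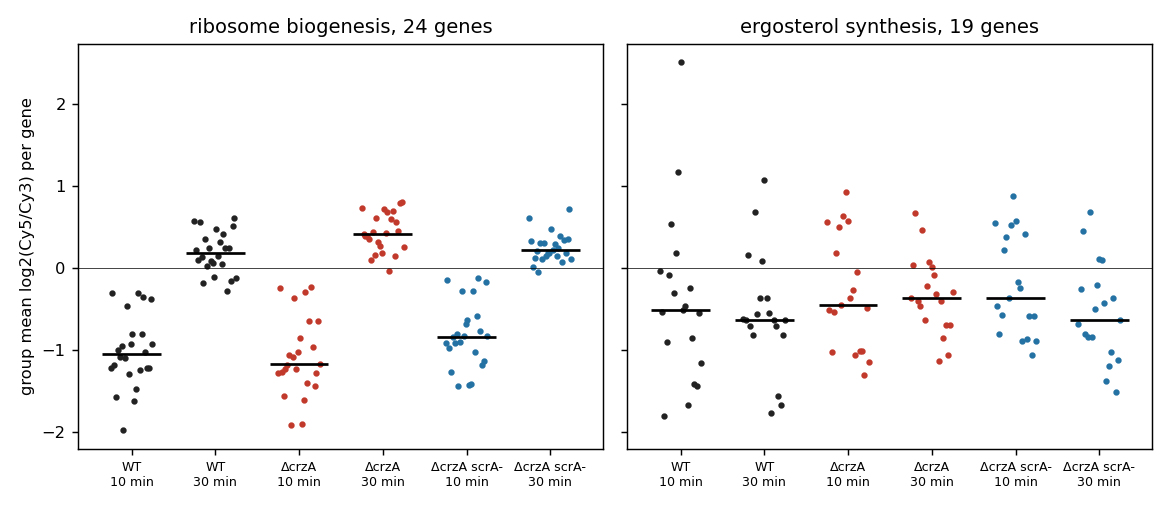
Group mean response as log2(Cy5/Cy3) of each ribosome biogenesis gene (24 genes, left) and each ergosterol synthesis gene (19 genes, right), by strain and time, with a line at the median. The ribosome biogenesis medians are −1.05, −1.17 and −0.83 at 10 min and 0.18 or above at 30 min.

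In the double mutant many of the same genes changed with time. There enaA increased by 3.61 (SE 0.51, adjusted p = 0.023), enaB by 2.11 (SE 0.21, adjusted p = 0.018) and cmkA by 1.19 (SE 0.22, adjusted p = 0.031). In all, 436 of 8636 genes were called (5.05%), 258 higher and 178 lower at 30 min, with AN8956 (4.54, SE 0.68, adjusted p = 0.024) at the top, but limma called 0 when only the arrays of this contrast were fitted. AN7674 (2.59) and AN1666 (2.34) also increased, and AN2020 (−2.44), AN4586 (−2.41), AN4051 (−2.40), AN9173 (−2.17) and creA (−2, SE 0.25, adjusted p = 0.018) decreased. Ribosome biogenesis had 2 of 24 genes higher (median 1.07, camera adjusted p = 8.8e-09; with the estimated correlation 0.54). The calcium list had 3 of 12 higher, also when adjusted over the list alone (median 0.27, camera adjusted p = 0.013; with the estimated correlation 0.33). The proteasome (median 0.23, camera adjusted p = 0.0013; with the estimated correlation 0.54) moved up, while chaperones (median −0.50, camera adjusted p = 0.014; with the estimated correlation 0.54) and ergosterol synthesis (4 of 19 lower, median −0.45, camera adjusted p = 0.021; with the estimated correlation 0.54) moved down. Across both strains 173 genes were called higher and 79 lower with time in both, where independent lists would share 12.7 and 5.32, and 1 gene was called in opposite directions. The double mutant's count was 51 without wild type 10 min replicate 1, 51 without its replicate 2, 657 without wild type 30 min replicate 1, 657 without its replicate 2, 274, 119 and 255 without ΔcrzA 10 min replicates 1, 2 and 3, 212 and 0 without double mutant 10 min replicates 1 and 2, and 4 without double mutant 30 min replicate 2. Without double mutant 30 min replicate 1 the balance turned, with 131 higher and 194 lower.

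The 10 min response was lower in ΔcrzA than in wild type for nearly all of the genes called; with array weights the count was 424, of which 133 were higher and 291 lower. The calcium/proton exchanger gene vcxA, the calcipressin gene cbpA, the phospholipase D gene pld2 and the kinase gene cmkA all responded less in ΔcrzA than in wild type. Of 8636 genes, 119 were called (1.38%), 113 lower and 6 higher in ΔcrzA, and 92 of the lower ones differed by an absolute log2 ratio of at least 1. The largest differences were AN10288 (−4.44, SE 0.31, adjusted p = 3.5e-04), AN6535 (−4.00, SE 0.31, adjusted p = 6.4e-04), AN11121 (−3.82) and AN0620 (−3.37). Among genes with a symbol the differences were pld2 (AN7334; −2.33, SE 0.20, adjusted p = 9.3e-04), cbpA (−2.05, SE 0.28, adjusted p = 0.0079), chsA (−2.02, SE 0.39, adjusted p = 0.047), erg4A (−1.92, SE 0.18, adjusted p = 0.0015) and vcxA (−1.83, SE 0.18, adjusted p = 0.0020). The differences for lap1 (−1.61), cmkA (−1.19, SE 0.20, adjusted p = 0.024) and dapB (−1.17) were also called, and the higher genes included AN6634 (1.73), AN1037 (0.77), AN1001 (0.73) and lcb2 (0.71). The difference for pmcB was −2.23 (SE 0.54, adjusted p = 0.12) and was not called, with 1 of 3 ΔcrzA arrays nearer to the wild-type values than the others. Of the 113 lower genes, 109 were called higher in wild type at 10 min, 101 were called higher in wild type at 30 min, and 33 were still called higher in ΔcrzA at 10 min.

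Some lists also differed between ΔcrzA and wild type. The calcium list had 2 of 12 lower, or 4 when adjusted over the list alone (median −0.14, camera adjusted p = 0.0065; with the estimated correlation 0.18, or 0.031 with each member taken by ID). Osmotic stress (median −0.37, camera adjusted p = 0.035; with the estimated correlation 0.45) and the proteasome (median −0.15, camera adjusted p = 0.029; with the estimated correlation 0.45) were called lower with 0 members called. Conidiation (median 0.15, camera adjusted p = 0.035; with the estimated correlation 0.31), glycolysis (median 0.28, camera adjusted p = 0.032; with the estimated correlation 0.45) and siderophores and iron (median 0.12, camera adjusted p = 0.036; with the estimated correlation 0.45) were called higher, also with 0 members called. With the preset correlation, the call held in 17 of 24 alternatives for conidiation and for glycolysis, and in 18 of 23 for osmotic stress. It held in 19 of 23 for the proteasome and for siderophores and iron. Ribosome biogenesis was not called (median −0.06, while camera's direction was up, adjusted p = 0.91). The count of 119 became 39 without wild type 10 min replicate 2 and 74 without ΔcrzA 10 min replicate 2.

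The double mutant differed from wild type at 10 min in much the same genes. Its responses were lower for cbpA (−2.42, SE 0.31, adjusted p = 0.0079), pld2 (−2.28, SE 0.22, adjusted p = 0.0023) and vcxA (−1.63, SE 0.20, adjusted p = 0.0075). In all, 86 of 8636 genes were called (0.996%), 83 lower and 3 higher, and 75 of the lower ones differed by an absolute log2 ratio of at least 1. AN10288 (−4.56, adjusted p = 6.7e-04), AN6535 (−3.79), AN11121 (−3.60) and AN7549 (−3.23) differed most, followed among genes with a symbol by erg4A (−1.94, adjusted p = 0.0032), lap1 (−1.77), pmcC (AN8399; −1.19, adjusted p = 0.019), dapB (−1.16) and cwc27 (−0.83). The higher genes were AN0981 (0.99), AN6820 (0.93) and AN4170 (0.73). The values of pmcB (−3.11, SE 0.59, adjusted p = 0.054), chsA (−1.98, adjusted p = 0.088) and cmkA (−0.93, adjusted p = 0.14) were not called. The calcium list had 1 of 12 lower, or 4 when adjusted over the list alone (median −0.19, camera adjusted p = 0.0023; with the estimated correlation 0.16, or 0.038 with each member taken by ID). The proteasome was called lower (median −0.20, camera adjusted p = 1.8e-04; with the estimated correlation 0.65), and ribosome biogenesis (median 0.19, camera adjusted p = 0.038; with the estimated correlation 0.67), ergosterol synthesis (median 0.30, camera adjusted p = 0.025; with the estimated correlation 0.65) and siderophores and iron (median 0.15, camera adjusted p = 0.031; with the estimated correlation 0.66) higher; without double mutant 10 min replicate 1 the ribosome biogenesis median was −0.21. The count of 86 became 27 without wild type 10 min replicate 2, 32 without double mutant 10 min replicate 1, 47 without its replicate 2 and 19 when only the arrays of the contrast were fitted.

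Most responses that were lower in the double mutant were also lower in ΔcrzA. Of the genes that differed from wild type at 10 min, 78 were lower in both mutants, 0 were higher in both and 0 went in opposite directions, where independent lists would share 1.09 lower and 0.00208 higher. The 113 genes lower in ΔcrzA were all negative in the double mutant, with a median difference of −1.53 in ΔcrzA and −1.50 in the double mutant. Both differences use the same wild-type arrays, which alone makes them correlate. Data simulated with that shared error and no true difference gave a mean overlap of 0.02 genes over 50 draws and a correlation across genes of 0.55, against 0.80 measured. The simulated errors were independent between arrays, while deviations of same-numbered arrays of the mutants at 10 min correlated at 0.47 and 0.34. The simulated values leave that likeness out and may be too low. With the wild-type arrays split, the 113 genes lowest in ΔcrzA against replicate 1 had a median difference of −1.82 in the double mutant against replicate 2, and −1.46 with the arrays exchanged. The overlap was 25 without wild type 10 min replicate 2, 30 without double mutant 10 min replicate 1, 45 without its replicate 2 and 19 when only the arrays of each contrast were fitted.

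**Figure D4:**
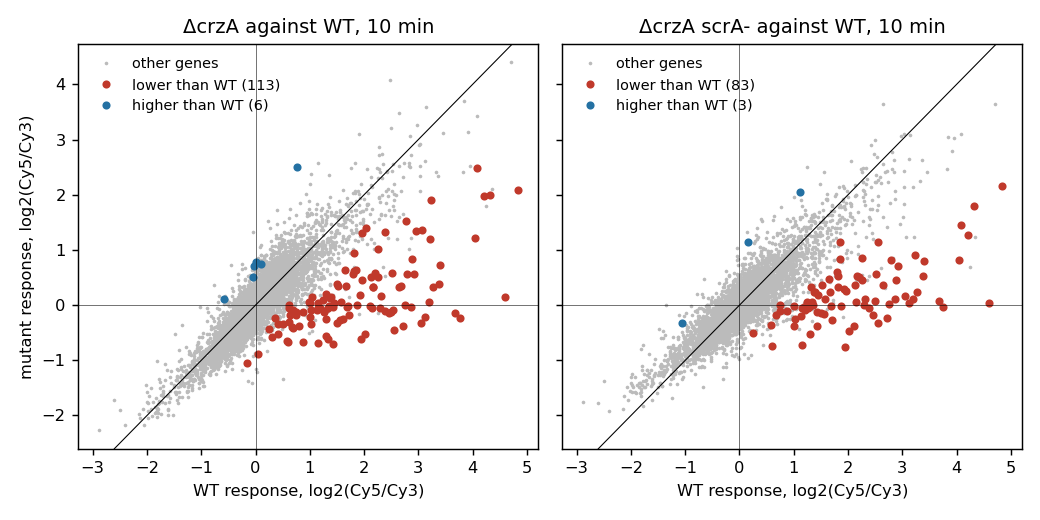
Response of each gene at 10 min as log2(Cy5/Cy3) in wild type (horizontal) against ΔcrzA (left) and the double mutant (right), with genes called lower in the mutant in red and higher in blue, and a line where both are equal. The 113 and 83 lower genes lie mostly at positive wild-type responses, and many have mutant responses near 0.

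The comparison of the double mutant with ΔcrzA at 10 min asked what the scrA- allele added. No gene was called by limma, and 208 of 8636 genes had an unadjusted p below 0.05. That is a smaller share than the 0.05 that genes without a difference would give on average. The differences were −0.88 for pmcB (SE 0.54, adjusted p = 1), 0.27 for cmkA and 0.19 for vcxA. For crzA the difference was 0.00, which says nothing about scrA- because both strains lack crzA. The largest differences among list members were niaD (−1.25, SE 0.51, adjusted p = 1) and fluG (1.03, adjusted p = 1). In data with known changes, the same fit called 72% of differences of log2 1 and 24% of differences of log2 0.5. Those data had errors independent between arrays. Deviations of same-numbered arrays of these 2 strains at 10 min correlated at 0.47 and 0.34, so the shares may differ on the real arrays.

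List shifts between the mutants were small. Camera called osmotic stress (median 0.28, adjusted p = 0.020; with the estimated correlation 0.56), gluconeogenesis (median 0.25, adjusted p = 0.015; with the estimated correlation 0.55), ribosome biogenesis (median 0.26, adjusted p = 0.0091; with the estimated correlation 0.71) and cytosolic ribosomal proteins (median 0.18, adjusted p = 0.015; with the estimated correlation 0.71) higher in the double mutant. Nitrogen assimilation (median −0.17, adjusted p = 0.0091; with the estimated correlation 0.55) and glycolysis (median −0.09, adjusted p = 0.047; with the estimated correlation 0.56) were called lower, and the glycolysis call held in 7 of 24 alternatives. No member of any of these lists was called. Without double mutant 10 min replicate 1, the median was −0.14 for ribosome biogenesis and −0.02 for cytosolic ribosomal proteins.

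At 30 min the double mutant still lacked part of the wild-type response. The exchanger gene vcxA (−1.67, SE 0.20, adjusted p = 0.0046), the calcium-transporting ATPase gene pmcC (−1.41, adjusted p = 0.0072) and pld2 (−1.41, adjusted p = 0.017) were lower than in wild type. The differences for cmkA (−0.16), enaA (0.15) and pmcB (−2.17, adjusted p = 0.14) were not called. In all, 137 of 8636 genes were called (1.59%), 114 lower and 23 higher, with 92 lower and 11 higher by an absolute log2 ratio of at least 1. AN6535 was lower by a large difference (−4.18, adjusted p = 4.6e-04). AN0903 (adjusted p = 5.2e-05), AN3403 (adjusted p = 5.2e-05) and AN0492 (adjusted p = 4.6e-04) were also called lower, but their fitted values are not exact sizes, because in the double mutant at 30 min they were well above background in Cy5 on 0 of 2 arrays. A smaller difference was called for alkA (−0.58), and admA was called lower with Cy3 signal not well above background. AN11609 (1.98, adjusted p = 0.0094), AN5468 (1.68), AN8169 (1.35) and AN6861 (1.26) were higher, as were bgt2 (1.23, adjusted p = 0.044), erg13 (1.19, adjusted p = 0.046), glfB (1.18, adjusted p = 0.025) and the chitin synthase gene chsF (0.57). No list was called, and the calcium list had 1 of 12 lower, or 2 when adjusted over the list alone (median −0.01, camera adjusted p = 0.50; with the estimated correlation 0.97). The count was 76 without wild type 30 min replicate 1, 80 without double mutant 30 min replicate 2 and 33 when only the arrays of the contrast were fitted.

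A large set of responses was shared across strains. At 10 min 780 genes were called higher in all 3 strains and 596 lower, where independent lists would share 36.8 and 20.6. Dye bias and the move to fresh medium, common to the arrays, also make calls agree at both times, so independent lists do not stand for no shared response to calcium. These shared genes included mfsA, treA, chiB, creA and midA among the rises, and erb1, rex4, nop7, rok1, tmpA and pmr1 among the falls. At 30 min wild type and the double mutant shared 754 higher and 408 lower genes, against 189 and 77.5 for independent lists, and 19 genes were called in opposite directions. Of the genes lower in the double mutant than in wild type, 42 were lower at both times, where independent lists would share 1.10, and all 42 were also lower in ΔcrzA at 10 min. Both times of a strain share a slide, and both mutants were compared with the same wild-type arrays at 10 min. Independent lists therefore do not stand for no strain difference either. The adjusted p values measure spread between these arrays only. Some Cy3 channels of a strain at 10 and 30 min were much alike, those of same-numbered arrays in wild type and the double mutant and those of 10 min replicate 3 and 30 min replicate 1 in ΔcrzA, and the labels do not say whether untreated cultures were shared.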

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

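The tests of dye bias and of a loss without crzA for the ribosome biogenesis genes were chosen only after the result was seen. The values here are named because the difference between times or strains itself passed its test (limma adjusted p below 0.05 for genes, camera for lists). Between strains, slide and strain cannot be told apart.

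Between 10 and 30 min in wild type 682 genes differed, and in the double mutant 436. In wild type the increases were AN8956 (4.19), AN7674 (3.31), AN4298 (2.92), rok1 (2.13), erb1 (2.01), erg9 (1.97), rex4 (1.80), trm10 (1.76) and rrp36 (1.73). The increases of enaA and enaB were also called, with fitted values of 3.64 and 2.04 that are not exact sizes, as at 10 min enaA was not well above background in Cy3 and enaB in neither channel. The decreases were sfh5 (−1.27), aclA (−1.33), erg4A (−1.43), flbC (−1.46), gpaB (−1.54), cbpA (−1.63), creA (−1.73), chsA (−1.87), AN8237 (−2.18), AN10350 (−2.34) and AN9074 (−2.60). AN6404 was also called lower, with a fitted value of −2.48 that is not an exact size, as Cy3 was not well above background at 30 min. In the double mutant the increases were AN8956 (4.54), enaA (3.61), AN7674 (2.59), AN1666 (2.34), enaB (2.11), rex4 (1.95), mirB (1.89), trm6 (1.65), rrp36 (1.48), rok1 (1.38) and cmkA (1.19). The decreases were sidA (−1.17), gpaB (−1.18), erg2 (−1.22), sfh5 (−1.26), hem13 (−1.35), flbA (−1.39), erg24B (−1.61), creA (−2), AN9173 (−2.17), AN4051 (−2.40), AN4586 (−2.41) and AN2020 (−2.44).

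Among lists, the median change with time was 1.27 for ribosome biogenesis in wild type. In the double mutant it was 1.07 for ribosome biogenesis, 0.27 for calcium signalling and transport, 0.23 for the proteasome, −0.45 for ergosterol synthesis and −0.50 for chaperones. With the estimated correlation none of these lists was called (adjusted p 0.33 to 0.65).

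At 10 min 119 genes differed between ΔcrzA and wild type, and 86 between the double mutant and wild type; at 30 min 137 differed between the double mutant and wild type. The differences of ΔcrzA were AN10288 (−4.44), AN6535 (−4.00), AN11121 (−3.82), AN0620 (−3.37), pld2 (−2.33), cbpA (−2.05), chsA (−2.02), erg4A (−1.92), vcxA (−1.83), lap1 (−1.61), cmkA (−1.19), dapB (−1.17), pmcC (−1.14), lcb2 (0.71), AN1001 (0.73), AN1037 (0.77) and AN6634 (1.73). Those of the double mutant at 10 min were AN10288 (−4.56), AN6535 (−3.79), AN11121 (−3.60), AN7549 (−3.23), cbpA (−2.42), pld2 (−2.28), erg4A (−1.94), lap1 (−1.77), vcxA (−1.63), pmcC (−1.19), dapB (−1.16), cwc27 (−0.83), AN4170 (0.73), AN6820 (0.93) and AN0981 (0.99). At 30 min they were AN6535 (−4.18), vcxA (−1.67), pmcC (−1.41), pld2 (−1.41), alkA (−0.58), chsF (0.57), glfB (1.18), erg13 (1.19), bgt2 (1.23), AN6861 (1.26), AN8169 (1.35), AN5468 (1.68) and AN11609 (1.98). AN0903, AN3403, AN0492 and admA were also called lower at 30 min. Their fitted values of −4.36, −4.14, −4.13 and −0.49 are not exact sizes, as the first 3 gave no Cy5 signal well above background in the double mutant and admA no such Cy3 signal in either strain.

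Lists that differed between ΔcrzA and wild type at 10 min had medians of −0.14 (calcium), −0.37 (osmotic stress), −0.15 (proteasome), 0.15 (conidiation), 0.28 (glycolysis) and 0.12 (siderophores and iron). For the double mutant against wild type the medians were −0.19 (calcium), −0.20 (proteasome), 0.19 (ribosome biogenesis), 0.30 (ergosterol synthesis) and 0.15 (siderophores and iron). For the double mutant against ΔcrzA they were 0.28 (osmotic stress), 0.25 (gluconeogenesis), 0.26 (ribosome biogenesis), 0.18 (cytosolic ribosomal proteins), −0.17 (nitrogen assimilation) and −0.09 (glycolysis). With the estimated correlation none of these lists was called (adjusted p 0.16 to 0.71), though with members taken by ID the calcium list was (0.031 for ΔcrzA and 0.038 for the double mutant against wild type), and without double mutant 10 min replicate 1 the median was −0.21 for ribosome biogenesis against wild type, −0.14 for it against ΔcrzA and −0.02 for cytosolic ribosomal proteins.

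The 113 genes with a lower calcium response in ΔcrzA at 10 min may include some whose response depends in part on crzA, with pld2, cbpA and vcxA among the 113, and 33 of them were still called higher in ΔcrzA. On these arrays the values argue against a higher untreated level in the mutants as the main cause. Of the mean difference −1.46% came from Cy3, and 110 of 113 genes were lower in Cy5. The 95% interval of −6.33 to 3.74% comes from resampling genes, so it does not measure the spread between arrays. Chance values of the shared wild-type arrays are excluded, since genes picked with wild type replicate 1 kept a median of −1.82 in the double mutant against replicate 2 (quartiles over genes −2.45 and −1.28). An effect of the wild-type slide cannot be told apart from strain: 95 of 155 genes (61.3%) differed between times when adjusted over these genes, but these were picked for passing at either time, which favours such a difference, and over all genes 8 were called. A crzA-dependent response and a slide effect both stay open.

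Ribosome biogenesis genes as a list fell at 10 min and returned by 30 min by camera, though not with the estimated correlation (adjusted p 0.48 to 0.72 at 10 min, 0.65 and 0.54 for time) and with 4 and 2 of 24 genes called for the return, which may be a transient response to the pulse or to fresh medium. Gene-specific dye bias would be equal at both times, so it cannot make the median change of 1.27 in wild type (quartiles over genes 0.88 and 1.67). It drops out of that change, which therefore cannot show whether the 10 min value was a fall from the preculture. A part of dye bias in the 10 min value stays open. Of 10000 random lists matched on signal, 0% had a median as low as in wild type at 10 min. Loess had already centred ratios near 0 at every signal level, so this test could not decide on normalization by signal. The wild-type median ran from −1.82 to −0.84 over the 23 alternatives, so a fall was seen in each but its size depended on the processing. A median difference of −0.06 between ΔcrzA and wild type (quartiles over genes −0.15 and 0.06) argues against a loss of the fall in ΔcrzA. In the double mutant, which also lacks crzA, the median difference to wild type was 0.19 (−0.21 to 0.58 over the alternatives). A partial loss there stays open. Calcium, fresh medium and handling between the preculture and the pulse stay open, as no array measured the move alone.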

How the results depend on the processing

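The control-culture block, the replicate block within a strain, and the lists with members taken by ID were chosen after seeing the data. Of 27507 recomputed values of the named genes, 25781 counted as unchanged, 1320 were no longer called, 396 became called and 10 reversed. Of 5302 recomputed list results, 5081 counted as unchanged, 119 were no longer called, 99 became called and 3 reversed. Only results called in the main fit could count as reversed. A result not called there counted as unchanged when its direction flipped, even if it was called the other way. Unless a reason is given, the cause was not tested.

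Over the settings other than leaving out an array or asking for an absolute log2 ratio of at least 1, the number called ranged from 2209 to 3756 for wild type at 10 min, 277 to 3564 at 30 min, 3395 to 4795 for ΔcrzA at 10 min, 139 to 682 at 30 min, 0 to 2210 for the double mutant at 10 min and 556 to 2578 at 30 min. It ranged from 1 to 1004 for the change with time in wild type, 0 to 851 in the double mutant, 104 to 424 for ΔcrzA against wild type, 19 to 116 for the double mutant against wild type at 10 min, 33 to 175 at 30 min and 19 to 104 for the overlap of both mutants. The comparison of both mutants gave 0 calls by limma in each setting. In the main fit 208 of 8636 genes had an unadjusted p below 0.05, a smaller share than genes without a difference would give on average.

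Fitting only the arrays of a contrast gave 3443 calls for wild type at 10 min, 277 at 30 min, 0 for the double mutant at 10 min, 556 at 30 min, 1 for time in wild type, 0 for time in the double mutant, 19 for the double mutant against wild type at 10 min, 33 at 30 min, and an overlap of 19. These fits have fewer residual degrees of freedom, and for ΔcrzA at 30 min none, so no value. Array weights gave 3756 for wild type at 10 min, 682 for ΔcrzA at 30 min, 70 for time in the double mutant, 424 for ΔcrzA against wild type (31.4% higher against 5.04%) and 90 for the double mutant against wild type at 30 min. Median centring gave 3564 for wild type at 30 min, 509 for ΔcrzA at 30 min and 164 for time in the double mutant. For ΔcrzA at 30 min, scaling between arrays gave 598, the authors' log2 values 139 and the control-culture block 343; that block gave 851 for time in the double mutant. Asking for an absolute log2 ratio of at least 1, which by construction lowers counts, left 696, 467, 697, 109, 457 and 515 genes for the 6 responses in the order above, and 315 and 204 for time in wild type and the double mutant.

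Median centring moved the median of all genes from 0.0154 to 0.117 in wild type at 10 min, from 0.0122 to 0.229 at 30 min, from 0.00621 to 0.147 in ΔcrzA at 30 min and from 0.00418 to 0.108 in the double mutant at 30 min. The share of calls that were higher became 83.5% against 58.1% for wild type at 10 min, 76.6% against 66.5% at 30 min, 74.4% against 50.4% for ΔcrzA at 10 min, 95.9% against 63.8% at 30 min, 83.7% against 55.9% for the double mutant at 10 min, 82.0% against 55.2% at 30 min, and 72.9% against 62.2% for time in wild type. In wild type it was 47.9% at 10 min and 52.0% at 30 min with Agilent's processed signals, and 47.9% and 52.1% with the authors' log2 values. Counts of rises against falls depend on the centring. Median centring reversed rpl17 (0.43 in wild type, 0.28 in ΔcrzA and 0.43 in the double mutant at 10 min), rps0 (0.07 and 0.18 in wild type at 10 and 30 min, 0.12 in ΔcrzA at 10 min), rpl16a (0.39), rpt4 (0.45) and sidJ (0.00) in ΔcrzA at 10 min, and pup1 (0.42) in the double mutant at 10 min. Without double mutant 10 min replicate 1, ribosome biogenesis reversed to −0.21 against wild type (highest without an array 0.58) and −0.14 against ΔcrzA (highest 0.74), and cytosolic ribosomal proteins to −0.02 against ΔcrzA (highest 0.40).

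Leaving out 1 array at a time gave 697 to 2374 for wild type at 10 min, 855 to 1921 at 30 min, 2230 to 3784 for ΔcrzA at 10 min, 0 to 336 at 30 min, 534 to 2063 for the double mutant at 10 min and 827 to 2484 at 30 min. The ranges were 80 to 1055 and 0 to 657 for time in wild type and the double mutant, 39 to 137 for ΔcrzA against wild type, 27 to 98 for the double mutant against wild type at 10 min, 76 to 140 at 30 min, 0 to 0 between the mutants and 25 to 90 for the overlap; the report names the arrays that move each count. Where this left a group with 1 array, that array was assumed to vary like the other groups. With the preset correlation, the calcium list call in wild type at 10 min held in 16 of 24 alternatives, its calls for both mutants against wild type at 10 min in 24 of 24, and the fall of ribosome biogenesis at 10 min in 23 of 23 in each strain. With the estimated correlation these calls were lost (adjusted p = 0.48, 0.18 and 0.16 for calcium, and 0.48, 0.72 and 0.62 for ribosome biogenesis). The calls lost most often were glycolysis between the mutants, held in 7 of 24, and septins, polarity and cytoskeleton in ΔcrzA at 30 min, held in 10 of 21. Only with members taken by ID, a choice made after seeing the data, was the calcium list lower with the estimated correlation, in ΔcrzA (adjusted p = 0.031) and the double mutant (0.038) against wild type at 10 min.

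The replicate number as a block gave 2304, 1942, 3717, 256, 1991 and 2507 calls for the 6 responses, 631 and 346 for time in wild type and the double mutant, 119, 84, 0 and 123 for the strain differences and an overlap of 79. Deviations of same-numbered arrays correlated across genes at 0.08 between times in wild type, 0.39 in the double mutant, 0.17 between wild type and the double mutant at 10 min and 0.28 at 30 min, and 0.47 and 0.34 between the mutants at 10 min. Between wild type and ΔcrzA at 10 min they were 0.23 and −0.02, and between wild type at 30 min and the mutants at 10 min −0.34 to −0.33, so the numbers were not taken as pairs. In wild type and the double mutant, the Cy3 channels of same-numbered arrays at 10 and 30 min differed by an SD of 0.071 to 0.166, against 0.27 to 0.356 for other numbers. In ΔcrzA the alike pair was 10 min replicate 3 with 30 min replicate 1 (0.072), and the pair numbered 1 differed by 0.253, so the control-culture block, which goes by number, does not join the alike pair there. With the number as a block within the strain, time gave 550 calls in wild type and 608 in the double mutant. The consensus correlation was 0.2 within control cultures and 0 within slides, so the slide block changed nothing. Each slide held 1 strain, so the group means take up any slide effect and this setting could not show one. The brightest-probe alternative does not apply with 1 probe per gene. Signal over background limits dim genes: 2507 genes were not tested, and ratios of genes near background, such as enaB before the pulse, are bounds.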

Other observations

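Whether rises and falls depend on crzA alike was a test chosen only after the result was seen; the test of how much of the response is kept was planned.

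Most of the strong early response was seen without crzA. Genes were picked by a rise of at least 1 in wild type replicate 1 at 10 min, leaving out those with little or no rise in replicate 2. Of the 467 genes picked, ΔcrzA kept a median of 75.8% of the rise measured in replicate 2 (quartiles 48.4 and 95%), and the double mutant 72.1%. In ΔcrzA 74 of these genes kept under 25% and 240 kept over 75%. Of 174 genes that fell as far in replicate 1 and also fell in replicate 2, ΔcrzA kept a median of 89.4% and the double mutant 73.7%. A response set mostly by crzA would keep less than 50%, so the values argue against that hypothesis for the measured response, which includes dye bias. A dye bias common to the strains counts as kept and raises these shares, and it, the fresh medium or other regulators may carry the rest.

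The genes called as responding less in the mutants lay among rises more than among falls. Of 493 genes called higher by at least 1 in wild type at 10 min, 90 (18.3%) were called lower in ΔcrzA. Of 203 genes called lower by at least 1, 0% were called higher in ΔcrzA by limma. In the double mutant 76 of the rises (15.4%) were called lower and 1 of the falls (0.493%) higher. On these shares alone the test first read against the hypothesis that crzA acts on rises and falls alike. A condition was added after the values were seen, because the shares restate the counts that prompted the test and falls were smaller than rises (at most −2.88 against 4.83). It asks that the median kept of falls exceed that of rises by more than the quartile range in both mutants. The excess was 13.6 in ΔcrzA (range 46.5) and 1.60 in the double mutant (range 50.4). That range is the spread of single genes, which a difference of medians could hardly exceed, so the condition cannot decide. Among genes picked on replicate 1, 74 of 467 rises and 3 of 174 falls kept under 25% in ΔcrzA, and 78 and 4 in the double mutant. These counts go the same way as the called shares, but strain is confounded with slide, so the question stays open.

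Presence of signal was compared between strains. In Cy3 alone, 39 genes were well above background on all 4 ΔcrzA arrays and none of the 4 wild-type arrays, 50 in the double mutant and not wild type, 14 in ΔcrzA and not the double mutant, 21 the reverse, and 4 and 3 in wild type and not ΔcrzA or the double mutant. In both channels, crzA alone was well above background on all 4 wild-type arrays and none of the 4 ΔcrzA arrays. Against the double mutant, crzA and AN1139 were. AN1139 and AN8950 were present in ΔcrzA and not in the double mutant, and AN2727 and AN7391 in the double mutant and not in ΔcrzA. In ΔcrzA but not wild type the genes were AN8950 and AN8969, and in the double mutant but not wild type there were 12. These genes were chosen after their values were seen, and the labels give no gene for scrA-, so none of them is offered as its locus.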
